A study of Arabidopsis thaliana with 30 samples.

How the data were processed

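The values are the deposited signals of 30 Affymetrix arrays of Arabidopsis seedlings, 1 for each of 3 replicate experiments in 5 conditions and 2 RNA pools. Per the labels the molecule was polyA RNA, 3 µg of RNA was used and biotin label was made with the One-Cycle cDNA kit. Treatments began when the day's light ended, and dim light was given. As deposited, the signals are log2 values that the authors made with RMA, per the submitters' processing notes. The RMA version, and which arrays were normalized together, are not given in the sources used here. Total array means lay between 5.754 and 5.805, and polysomal means between 4.33 and 5.37. The polysomal arrays lie below the total arrays by 0.41 in air at 2 h, 1.24 after 2 h of hypoxia, 0.416 in air at 9 h, 1.43 after 9 h of hypoxia and 0.578 after recovery, and the step that gave this is not given in the sources used here. Array images and probe-level signals were not analysed here.

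Of 22810 probe sets, 64 controls were left out and 22746 tested. A gene name was taken only from the probe table used here: 13513 probe sets had 1 gene, 503 had several and 8730 had none and are not named. Where a gene had several probe sets, the one with the highest mean over all 30 arrays stood for it, which gave 13355 genes, and 13459 probe sets had a locus in the RefSeq gene table. Among the genes chosen to be named wherever measured, ADH1, PDC1, SUS4 and RPL18B had no named probe set and were not analysed here.

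Samples, groups, model, thresholds, alternatives and the first set of gene lists were written down before the data were examined. The model was limma (version 3.58.1, R 4.3.3) with 1 mean for each of the 10 groups on all 30 arrays, 20 residual degrees of freedom and moderated t tests. Adjusted p values are Benjamini-Hochberg over all 22746 probe sets in each comparison, and the threshold was 0.05. No filter was applied. Comparisons were hypoxia against air at 2 h and 9 h, recovery against 9 h of hypoxia and against 9 h of air, each in total and in polysomal RNA. The polysomal change minus the total change (association change) was tested for each. Others were the 9 h effect minus the 2 h effect and 9 h against 2 h of air, both in total RNA, and polysomal against total RNA in air. Standard errors are those of the model.

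The 20 gene lists were core hypoxia (45 genes, 19 named), fermentation (15, 2), glycolysis (32, 10), ethylene (24, 1), heat shock (20, 5), oxidative stress (19, 4), stress transcription factors (19, 2), jasmonate (17, 0), carbon starvation (21, 3), ribosomal proteins (60, 27) and translation factors (15, 1). The rest were nuclear photosynthesis (38, 7), nuclear genes of mitochondrial respiration (13, 6), clock (18, 1), cell wall (16, 2), cell cycle (17, 1), root markers (10, 2), seed genes (8, 0), plastid-encoded (69, 69) and mitochondrion-encoded genes (16, 16). Lists with at least 5 named genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The others are described by gene, and the jasmonate and seed lists had no named member. A further 17 lists, marked as added, were defined after gene names and array-level summaries had been seen but before any fold change. They were adjusted as a family of their own, and 1 of them is not reported here. List members came from general knowledge and not from a database.

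Genes were named by a rule fixed beforehand, which was later also applied to mean-centred values in the comparisons with polysomal arrays. That step was added after the data were seen, and overlap of replicates was still judged on the deposited values. The largest mean-centred changes named are thus the largest among genes without overlap on the deposited values. The 5 largest rises and 5 largest falls were taken among genes that passed the test and whose replicates did not overlap between groups, which for 3 against 3 arrays happens by chance in 10% of cases for 1 gene. From each list up to 4 passing members with the largest changes were added, and further members are given by value.

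Replicate numbers were checked for pairing, as a hint from the data, through the correlation of same-numbered arrays' deviations from their group means. Every pair was over 0.1 for 2 h hypoxia against air in total RNA (0.13 to 0.47), recovery against 9 h hypoxia (0.222 to 0.442) and against 9 h air (0.115 to 0.295) in total RNA, for 9 h hypoxia (0.106 to 0.18) and recovery against 9 h hypoxia (0.237 to 0.269) in polysomal RNA, and for the 2 air controls (0.216 to 0.344). Total and polysomal arrays of the same condition and number were correlated in all 15 pairs (0.133 to 0.589). The labels speak of independent replicate experiments and do not say that a number marks a shared day.

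Alternatives written beforehand were leaving out the dimmest 40 percent of probe sets, fitting only the groups compared or only the arrays of 1 pool, subtracting array medians, quantile normalization again, the replicate number as a block, paired polysomal minus total differences, a trended robust fit, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each array and each replicate number. Subtracting the array mean, paired differences on those values and for polysomal against total RNA, and a direct test between the 2 hypoxic groups were added after the data were seen. No arrays looked like copies: the smallest median absolute difference between replicates was 0.102. Within groups, correlations between arrays were 0.987 to 0.997. In a simulation on these group sizes the test found 60% of 1.5-fold and 98% of 2-fold changes at 2 h in total RNA, with 10 unchanged probe sets called. For the association change at 2 h it found 20% and 81%, with 5 unchanged probe sets called. Only 100 probe sets of each size were changed among 22746, with independent noise and no shift between arrays. In the real comparisons far more probe sets passed, so these shares hold for the simulated setting only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.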

Results

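The series compares 7-day-old Arabidopsis seedlings that carry a 35S:His6FLAG-RPL18B transgene, a tagged ribosomal protein through which polysomes can be pulled down. Per the labels, seedlings were held in air or under hypoxia for 2 h or 9 h, or were given 1 h of recovery in air after 9 h of hypoxia. Total RNA and immunopurified polysomal RNA of each condition were hybridised to Affymetrix arrays in 3 independent replicate experiments, which gives 30 arrays in 10 groups of 3. All 30 arrays were used, and 22746 probe sets were tested after 64 control probe sets were left out. Changes are log2 changes with a standard error (SE) from 3 arrays per group, and a probe set is said to rise or fall where its limma adjusted p was under 0.05.

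Total RNA arrays had nearly the same mean over all probe sets (5.754 to 5.805, log2), while polysomal arrays did not. The polysomal group means were 5.364 in air at 2 h and 4.536 after 2 h of hypoxia. At 9 h they were 5.358 in air and 4.342 under hypoxia, and 5.196 after recovery (n = 3 arrays each; standard deviation within a group at most 0.016). Probe sets for the hybridisation controls, which are spiked into every sample, also lay lower on the hypoxic polysomal arrays: 8.656 against 9.477 at 2 h, and 8.643 against 9.339 at 9 h. On the total arrays the same controls were at 9.833 against 9.544 and at 9.993 against 9.717. The array means and the control means are drawn in the figure of array levels. Because of this shift, changes in polysomal RNA are given below after each array's mean was subtracted ("mean-centred"). This alternative was chosen after the data were seen, and counts on the deposited log2 values stand beside them. Mean-centred changes are relative to all probe sets. If the shift holds a difference in polysome content, mean-centring removes it.

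**Figure D1:**
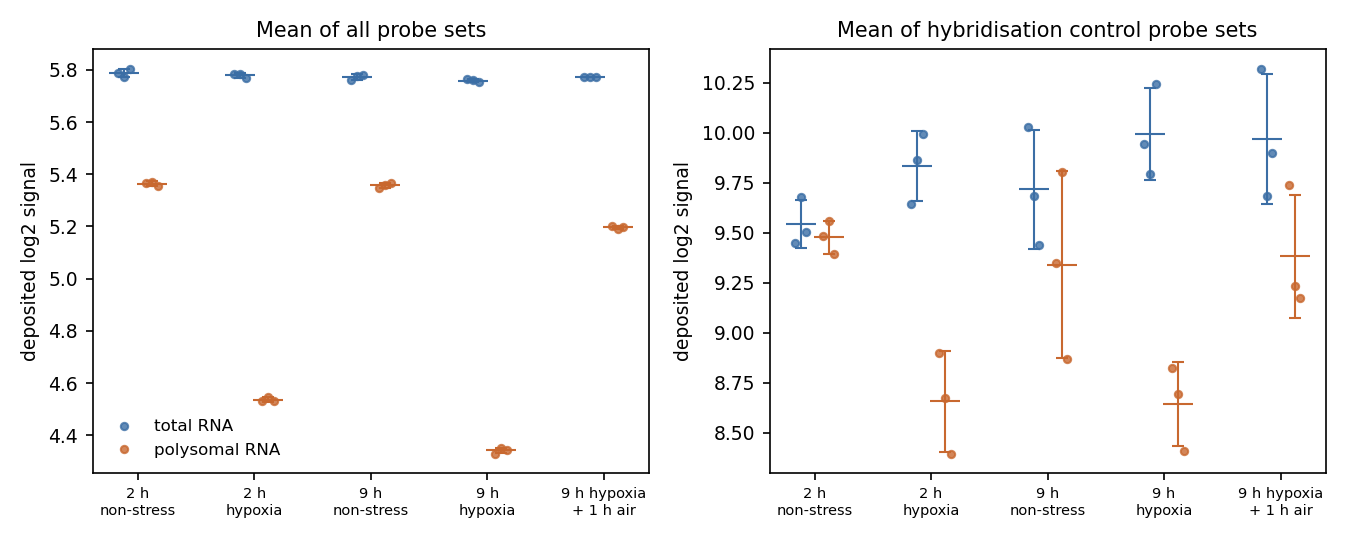
Mean of all probe sets (left) and of the hybridisation control probe sets (right) on each array, by condition, for total and polysomal RNA. Points are arrays (n = 3 per group), and bars are means ± SD.

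After 2 h of hypoxia the largest rises in total RNA were in genes of the known low-oxygen response. AT5G10040 rose by 6.69 ± 0.221 (SE, n = 3 arrays per group), the calmodulin-like gene CML38 by 6.36 ± 0.265, AT1G19530 by 5.88 ± 0.231, AT3G23170 by 5.52 ± 0.16 and AT4G24110 by 5.36 ± 0.257. Of the 19 core hypoxia genes that could be named, 18 rose, with a median of 4.83 (camera adjusted p = 1.24e-56, and adjusted p = 2.35e-06 with an estimated correlation). The exception was AT5G45960, and adjusted over the list alone 18 rose as well. AT3G10040, which encodes the hypoxia response attenuator HRA1, rose by 4.86, AT4G10270 by 5.22 and AT1G33055 by 5.27. This list was written from general knowledge of the published hypoxia response, which can rest in part on these samples, so it is not independent evidence of direction. Both nameable fermentation genes rose: PDC2, a pyruvate decarboxylase, by 2.73, and AT4G17260, a lactate dehydrogenase, by 2.15. The values of the core genes at 2 h, at 9 h and after recovery are drawn in the figure of core hypoxia genes.

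**Figure D2:**
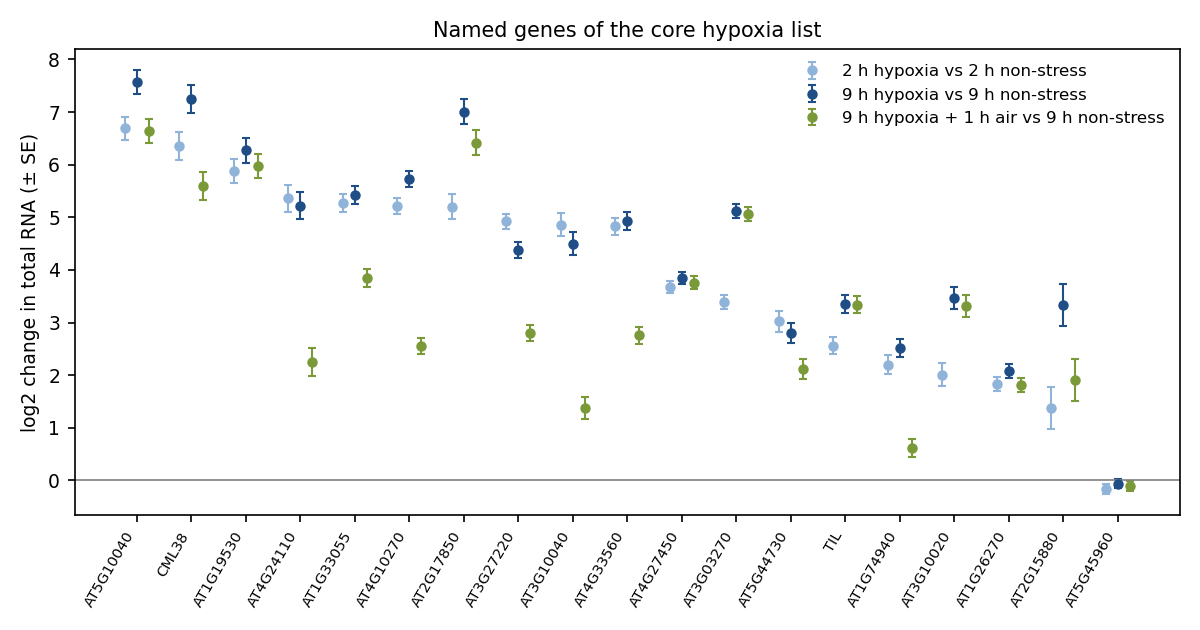
Log2 change ± SE in total RNA of the 19 named core hypoxia genes after 2 h of hypoxia, after 9 h of hypoxia and after recovery, each against air (n = 3 arrays per group).

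Among other groups at 2 h, 3 of 5 heat shock genes rose (4 adjusted over the list alone), with a median of 1.3 (adjusted p = 0.00223, and adjusted p = 0.284 with an estimated correlation). They were the small heat shock protein genes AT5G51440 (mitochondrial, 2.61), AT5G37670 (1.3) and AT2G29500 (1.17). Of the 16 mitochondrion-encoded genes 7 rose (10 adjusted over the list alone), with a median of 0.43 (adjusted p = 1.1e-05, and adjusted p = 0.0629 with an estimated correlation). They included ccb452 (1.55), cox1 (1.03) and nad9 (0.87). The zinc-finger factor STZ rose by 2.76 and WRKY53 was at 0.32, so that 1 of 2 stress transcription factors rose. Among carbon starvation genes 2 of 3 rose (3 adjusted over the list alone), namely IVD (1.55) and MCCA (1.79) of leucine breakdown. Of 4 oxidative stress genes 2 rose, AT2G21640 by 0.83 among them, and the NAD(P)H dehydrogenase gene NDB2 fell by 0.58.

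The largest falls at 2 h were in AT5G57760 (-2.63 ± 0.237), AT3G28040 (-2.12 ± 0.278), AT5G04960 (-2.12 ± 0.134), EXPA18, a root-hair expansin (-2.09 ± 0.138), and AT5G58900 (-2.08 ± 0.236; SE, n = 3 arrays per group). Both root markers fell: EXPA7, another root-hair expansin, by 1.01, and the root beta-glucosidase gene PYK10 by 0.38. EIN3 of ethylene signalling fell by 0.44, the translation factor gene EIF4A-2 by 0.36 and the cell wall gene XTH16 by 0.65. The clock gene GI was at 0.1 and the cell cycle gene AUR1 at -0.06, and neither passed. The 10 glycolysis genes moved in both directions, with 1 rise and 1 fall (2 and 2 adjusted over the list alone; median 0.07, adjusted p = 0.926). The pyruvate kinase gene AT5G08570 rose by 0.34 and AT1G20950, a phosphofructokinase subunit, fell by 0.52. Cytosolic ribosomal proteins had a median of -0.11 over 27 genes, and 1 of them fell, but only when adjusted over all probe sets and not over the list alone. Their adjusted p was 0.0548, and 0.0233 with the replicate number as a block. In the 6 nuclear genes of mitochondrial respiration 1 rose (CYTC-2, 0.67) and 1 fell (SDH1-1, -0.65), the same when adjusted over the list alone (median -0.11, adjusted p = 0.653). Medians of the 7 nuclear photosynthesis genes (-0.04, adjusted p = 0.926) and the 69 plastid-encoded genes (0.14, adjusted p = 0.127) stayed near 0.

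In all, 1866 probe sets rose and 2843 fell in total RNA at 2 h, and 577 and 347 of them changed at least 2-fold. The sum of 4709 dropped to 3109 when total 2 h hypoxia replicate 3 was left out and to 1913 without replicate 3 of every group. The calls of PYK10, XTH16, EIF4A-2, EIN3, AT5G37670, AT2G29500, NDB2, AT2G21640, AT5G08570, AT1G20950, CYTC-2, SDH1-1 and nad9 also ended when at least 1 array or replicate number was left out.

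After 9 h of hypoxia core genes were again far above their level in air. AT5G10040 rose by 7.57 ± 0.221, CML38 by 7.25 ± 0.265, AT2G17850 by 7.01 ± 0.237, AT1G19530 by 6.27 ± 0.231 and AT1G63530 by 6.22 ± 0.414 (SE, n = 3 arrays per group). Of the 19 core genes 18 rose (18 adjusted over the list alone), with a median of 4.5 (adjusted p = 7.59e-26, and adjusted p = 0.000514 with an estimated correlation). AT4G10270 was up by 5.73, AT1G33055 by 5.43, AT3G03270 by 5.12 and AT3G10040 by 4.5. PDC2 rose by 5.33 and AT4G17260 by 2.44. All 5 heat shock genes rose (5 adjusted over the list alone): AT1G53540 by 5.44, AT2G29500 by 5.09, AT5G51440 by 4.69, ATHSP22.0 by 4.01 and AT5G37670 by 3.9. Their median was 4.69 (adjusted p = 7.29e-06, and adjusted p = 0.0789 with an estimated correlation).

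Mitochondrion-encoded transcripts rose in total RNA at 9 h: 14 of 16 genes (14 adjusted over the list alone), with a median of 0.99 (adjusted p = 7.45e-07, and adjusted p = 0.0361 with an estimated correlation). The largest were cox1 (2.1), ccb452 (1.88), nad5 (1.74) and cox2 (1.47). Plastid-encoded genes had a median of 0.29, and 9 of 69 rose (3 adjusted over the list alone; adjusted p = 0.0911). Spiked Bacillus control probe sets also lay higher on the total hypoxia arrays, at 6.892 against 5.826. All 3 carbon starvation genes rose: IVD by 2.36, MCCA by 2.18 and MCCB by 0.78. Both stress transcription factors rose, STZ by 3.53 and WRKY53 by 1.6. Among oxidative stress genes AT2G21640 rose by 1.46, NDB2 fell by 0.99 and GSTU25 was at 0.03.

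The largest falls at 9 h were in AT3G54400 (-4.18 ± 0.207), AT4G30170, a class III peroxidase (-4.08 ± 0.259), AT1G30870, another class III peroxidase (-3.47 ± 0.204), AT4G11190 (-3.41 ± 0.211) and the peroxidase gene AT4G26010 (-3.37 ± 0.17; SE, n = 3 arrays per group). Cytosolic ribosomal protein genes fell: 23 of 27 (24 adjusted over the list alone), with a median of -0.56 (adjusted p = 1.93e-09, and adjusted p = 0.14 with an estimated correlation). Examples are AT5G60670 (-1.5), AT5G39850 (-1.47), AT3G11250 (-1.2) and AT2G45710 (-1.16). EIF4A-2 fell by 0.74. Of 7 nuclear photosynthesis genes 4 fell (4 adjusted over the list alone), LHCB4.2 by 2.05, with a median of -0.25 (adjusted p = 0.0324, and adjusted p = 0.14 with an estimated correlation). Both root markers (EXPA7 -1.45, PYK10 -1.04) and both cell wall genes (EXPA8 -1.81, XTH16 -1.86) fell, as did AUR1 (-0.41). EIN3 (-0.22) and GI (-0.2) did not pass. Glycolysis was split, with 5 rises and 3 falls (5 and 3 adjusted over the list alone; median 0.29, adjusted p = 0.833). The pyruvate kinase genes AT5G08570 (1.37) and AT5G63680 (1.18) rose. The phosphofructokinase subunit genes AT1G12000 (-1.17) and AT1G20950 (-1.14) and the enolase gene ENOC (-1.11) fell. Of the 6 nuclear respiration genes 1 rose (CYTC-2, 0.77) and 3 fell, SDH1-1 by 0.59, the same when adjusted over the list alone (median -0.31, adjusted p = 0.345).

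At 9 h 4849 probe sets rose and 5563 fell (1418 and 1935 at least 2-fold). With each array's median subtracted the balance was 8994 rises and 4385 falls, so the direction of small changes depends on the scaling. The calls of AUR1 (-0.41) and MCCB (0.78) ended when at least 1 array or replicate number was left out. Of the 1866 probe sets that rose at 2 h, 1501 also rose at 9 h (398 expected for independent calls), and 2358 of the 2843 that fell also fell (695 expected). Across probe sets the changes at 2 h and 9 h had a correlation of 0.763.

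The change against air at 9 h differed from that at 2 h for many genes, through the hypoxic groups, the air controls or both. The largest differences upward were in AT1G63530 (4.57 ± 0.585), AT1G53540 (4.06 ± 0.759), AT2G29500 (3.92 ± 0.483), AT2G20500 (3.51 ± 0.378) and AT1G72800 (3.43 ± 0.496; SE from 3 arrays in each of 4 groups). The 5 heat shock genes were all higher at 9 h (5 adjusted over the list alone), with a median difference of 3.32 (adjusted p = 5.23e-06, and adjusted p = 0.112 with an estimated correlation). PDC2 was higher by 2.61, of which 0.46 ± 0.121 lay between the hypoxic groups and 2.14 was a fall between the air controls. Among core hypoxia genes 6 of 19 were higher (6 higher and 1 lower adjusted over the list alone), including AT2G15880 (1.97), AT2G17850 (1.81) and AT3G03270 (1.73). Their median difference was 0.33 (adjusted p = 0.00523, and adjusted p = 0.278 with an estimated correlation). Between the hypoxic groups AT2G15880 differed by 1.64, AT2G17850 by 0.95 and AT3G03270 by 1.65, and between the air controls by -0.33, -0.86 and -0.08. Of the 19 core genes 8 rose and 5 fell between the hypoxic groups (median 0.13, adjusted p = 0.428), and the median between the air controls was -0.33. Mitochondrion-encoded genes were higher by a median of 0.41 (5 of 16, 6 adjusted over the list alone; adjusted p = 0.000459, and adjusted p = 0.112 with an estimated correlation). The largest differences downward were in AT3G54400 (-2.92 ± 0.292), AT5G62340 (-2.88 ± 0.211), AT4G11190 (-2.74 ± 0.298), AT4G30170 (-2.71 ± 0.366) and ZW9 (-2.71 ± 0.317). Ribosomal protein genes were lower by a median of 0.36 (10 of 27, 10 adjusted over the list alone; median -0.36, adjusted p = 1.84e-10, and adjusted p = 0.112 with an estimated correlation). Photosynthesis genes were at -0.26 (2 of 7 lower, 3 adjusted over the list alone; adjusted p = 0.00613, and adjusted p = 0.112 with an estimated correlation), with LHCB4.2 at -1.71. This lay in the air controls, whose median rose by 0.32 (LHCB4.2 by 1.71), while the hypoxic groups differed by a median of 0.06 (adjusted p = 0.738). Compared directly, a test added after the results were seen, the hypoxic groups differed by a median of 3.41 in heat shock genes (adjusted p = 3.03e-06, and adjusted p = 0.151 with an estimated correlation), 0.47 in mitochondrion-encoded genes (adjusted p = 0.000207, and adjusted p = 0.151 with an estimated correlation) and -0.38 in ribosomal protein genes (adjusted p = 5.5e-09, and adjusted p = 0.202 with an estimated correlation). Glycolysis had 2 higher and 3 lower genes (3 and 3 adjusted over the list alone; median 0.07, adjusted p = 0.946). The difference passed for 1848 probe sets upward and 2299 downward (2801 and 1842 with each array's median subtracted). The sum of 4147 dropped to 2279 without replicate 2 and to 2047 without replicate 3, and the call of AT2G15880 ended in at least 1 leave-out.

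One hour of recovery in air lowered much of the core response and raised other genes within total RNA. AT4G10270 fell by 3.17 ± 0.154 from its level at 9 h of hypoxia, AT3G23170 by 3.15 ± 0.16, AT3G10040 by 3.12 ± 0.214, AT4G24110 by 2.97 ± 0.257 and AT5G42200 by 2.74 ± 0.217 (SE, n = 3 arrays per group). Of the 19 core genes 11 fell (12 adjusted over the list alone), with a median of -0.94 (adjusted p = 4.02e-11, and adjusted p = 0.0329 with an estimated correlation). The lactate dehydrogenase gene AT4G17260 fell by 0.76, while PDC2 was at -0.27. Mitochondrion-encoded genes fell: 10 of 16 (11 adjusted over the list alone), with a median of -0.57 (adjusted p = 1.26e-06, and adjusted p = 0.0371 with an estimated correlation). Examples are ccb452 (-1.6), cox1 (-1.35) and nad5 (-1.05). The largest rises were in AT2G47440 (3.44 ± 0.171), the expansin-like gene EXLA1 (3.12 ± 0.253), AT4G35320 (2.85 ± 0.183), AT3G56200 (2.72 ± 0.182) and AT2G44670 (2.7 ± 0.182).

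Heat shock genes did not come back down with recovery: 3 of 5 rose further (4 adjusted over the list alone), with a median of 1.36 (adjusted p = 0.0075, and adjusted p = 0.39 with an estimated correlation). AT2G29500 rose by 1.41, ATHSP22.0 by 1.36 and AT5G37670 by 1.29. NDB2 (0.94), EIF4A-2 (0.73), XTH16 (0.73), EIN3 (0.62) and GI (0.55) also rose, and IVD fell by 0.56. The 27 ribosomal protein genes had a median of -0.02 with 2 falls, which passed over all probe sets but not over the list alone, while their test pointed up, so that median and test differ in sign (adjusted p = 0.986). The 10 glycolysis genes had a median of 0.08 (adjusted p = 0.442). Plastid-encoded genes had a median of -0.29 (adjusted p = 0.0524, and 0.0283 with the replicate number as a block). Recovery raised 2852 probe sets and lowered 2195 (645 and 237 at least 2-fold), or 2176 and 4516 with each array's median subtracted. The sum of 5047 dropped to 2640 without replicate 3, and the calls of ATHSP22.0, AT5G37670, AT2G29500, XTH16, AT4G17260, IVD and GI ended when at least 1 array or replicate number was left out.

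Against the 9 h air control, recovered seedlings still carried most of the response. AT1G53540 was higher by 6.85 ± 0.536, AT5G10040 by 6.64 ± 0.221, AT2G29500 by 6.5 ± 0.342, AT2G17850 by 6.42 ± 0.237 and AT1G52560 by 6.31 ± 0.291 (SE, n = 3 arrays per group). All 5 heat shock genes were up (5 adjusted over the list alone), with a median of 5.37 (adjusted p = 2.57e-08, and adjusted p = 0.0352 with an estimated correlation). Core genes were up in 18 of 19 cases (18 adjusted over the list alone) with a median of 2.8 (adjusted p = 5.85e-24, and adjusted p = 0.000803 with an estimated correlation). AT4G10270 was up by 2.56 and AT3G10040 by 1.38, PDC2 by 5.07, AT4G17260 by 1.67 and STZ by 3.99. The largest falls were in AT4G30170 (-4.63 ± 0.259), AT4G11190 (-3.96 ± 0.211), AT4G26010 (-3.91 ± 0.17), AT1G30870 (-3.77 ± 0.204) and ZW9 (-3.76 ± 0.224). Ribosomal protein genes were down in 21 of 27 cases (24 adjusted over the list alone; median -0.48, adjusted p = 2.07e-10, and adjusted p = 0.16 with an estimated correlation). Mitochondrion-encoded genes were up in 7 of 16 (7 adjusted over the list alone; median 0.33, adjusted p = 0.0136, and adjusted p = 0.229 with an estimated correlation). Photosynthesis genes had 5 falls among 7 (5 adjusted over the list alone, median -0.3, adjusted p = 0.059), and glycolysis had 3 rises and 3 falls (4 and 3 adjusted over the list alone, median 0.19, adjusted p = 0.783). In all 4134 probe sets were up and 4693 down (1302 and 1349 at least 2-fold). Of the 4849 probe sets that rose at 9 h of hypoxia, 2946 were still up, and 1371 fell between hypoxia and recovery. Of the 5563 that fell, 3762 were still down, and 1730 rose on recovery. These pairs of comparisons share arrays, so no count expected by chance is given. Sharing alone gives a correlation of 0.499 between the 9 h change and the remaining change, where 0.843 was found. Between the 9 h change and the change on recovery it gives -0.5, where -0.401 was found, so that correlation was no stronger than from sharing alone. The covariance there was -0.138, against -0.011 from sharing.

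Between the 2 air controls, 9 h against 2 h, changes in total RNA were fewer. AT2G41250 (3.54 ± 0.149), AT1G55960 (3.09 ± 0.203) and AT1G69570 (2.5 ± 0.196) rose, while AT3G62550 (-3.45 ± 0.132), CCL (-3.12 ± 0.137) and AT4G16146 (-3.11 ± 0.157; SE, n = 3 arrays per group) fell. Photosynthesis genes rose in 5 of 7 cases (5 adjusted over the list alone; median 0.32, adjusted p = 2.56e-06, and adjusted p = 0.00619 with an estimated correlation), LHCB4.2 by 1.71. Of the core hypoxia genes 7 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.33, adjusted p = 0.00703, and adjusted p = 0.632 with an estimated correlation). PDC2 fell by 2.14, and EXPA8 rose by 2.16. In all 640 probe sets rose and 965 fell, and the sum of 1605 dropped to 1016 without replicate 2 and to 742 without replicate 3.

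In polysomal RNA the core hypoxia genes rose at 2 h, relative to the shift of all probe sets. Mean-centred, AT5G10040 rose by 7.12 ± 0.222, CML38 by 6.5 ± 0.266, AT4G24110 by 5.34 ± 0.258, AT2G17850 by 5.18 ± 0.238 and AT1G19530 by 5.11 ± 0.231 (SE, n = 3 arrays per group). Of the 19 core genes 18 rose (18 adjusted over the list alone), with a median of 4.48 (adjusted p = 2.17e-37, and adjusted p = 5.35e-05 with an estimated correlation). PDC2 rose by 3.43 and AT4G17260 by 2.46. Unlike in total RNA, 9 of 10 glycolysis genes rose (9 adjusted over the list alone), with a median of 0.57 (adjusted p = 6.34e-07, and adjusted p = 0.0248 with an estimated correlation), PPDK by 1.7. This is a rise relative to all probe sets: on the deposited log2 values the glycolysis median was -0.26, with 1 rise and 6 falls. The 5 heat shock genes rose (5 adjusted over the list alone; median 1.83, adjusted p = 0.000276, and adjusted p = 0.153 with an estimated correlation). The largest falls were in AT5G57760 (-4 ± 0.239), AT3G53250 (-2.94 ± 0.354), AT5G58900 (-2.62 ± 0.234), AT1G23030 (-2.33 ± 0.2) and AT3G55170, a ribosomal protein gene (-2.25 ± 0.239). Ribosomal protein genes fell in 19 of 27 cases (23 falls and 1 rise adjusted over the list alone), with a median of -0.56 (adjusted p = 5.2e-09, and adjusted p = 0.153 with an estimated correlation). The mitochondrion-encoded genes had a median of 0.04 (adjusted p = 0.718). Mean-centred, 3566 probe sets rose and 4012 fell, against 623 and 20042 on the deposited log2 values, where the median change of all probe sets was -0.846 and the call of PPDK ended in at least 1 leave-out. Of the probe sets that rose in total RNA at 2 h, 1302 also rose here (293 expected for independent calls), and 1273 fell in both (501 expected). The expected counts leave out that total and polysomal arrays of the same condition and number were correlated.

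At 9 h of hypoxia ribosomal protein genes fell in polysomal RNA: all 27 of them (27 adjusted over the list alone), with a mean-centred median of -1.33 (adjusted p = 2.73e-20, and adjusted p = 0.0364 with an estimated correlation). AT5G60670 fell by 2.85 and AT5G16130 by 2.21. AT5G67510, which encodes a ribosomal protein of the L26 family, fell most of all nameable genes (-3.69 ± 0.192), followed by AT3G53250 (-3.38 ± 0.354), AT5G57760 (-3.37 ± 0.239), AT5G12050 (-3.36 ± 0.208) and EXPA4, an expansin (-3.29 ± 0.27). The largest rises were in AT5G10040 (7.71 ± 0.222), CML38 (6.87 ± 0.266), AT1G53540 (6.78 ± 0.539), AT2G17850 (6.73 ± 0.238) and AT1G63530 (6.66 ± 0.417; SE, n = 3 arrays per group). Core genes rose in 18 of 19 cases (18 adjusted over the list alone; median 4.11, adjusted p = 2.21e-22, and adjusted p = 0.00129 with an estimated correlation). PDC2 rose by 6.53 and AT4G17260 by 3.22. All 5 heat shock genes rose (5 adjusted over the list alone; median 5.04, adjusted p = 1.08e-05, and adjusted p = 0.0811 with an estimated correlation). Glycolysis had 7 rises and 2 falls (7 and 2 adjusted over the list alone; median 0.92, adjusted p = 0.000738, and adjusted p = 0.0958 with an estimated correlation), where the deposited median was -0.1. Mitochondrion-encoded genes had a median of 0.19 (adjusted p = 0.377), where total RNA had shown 0.99. Mean-centred, 5142 probe sets rose and 5744 fell (7611 and 5020 with each array's median subtracted), against 1031 and 20209 on the deposited log2 values with an all-gene median of -0.969.

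On recovery ribosomal protein genes rose again in polysomal RNA: 22 of 27 rose and 2 fell against 9 h of hypoxia (22 and 2 adjusted over the list alone), with a mean-centred median of 0.66 (adjusted p = 6.38e-09, and adjusted p = 0.195 with an estimated correlation). Core hypoxia genes fell in 13 of 19 cases and 1 rose (15 and 1 adjusted over the list alone; median -1.08, adjusted p = 5.22e-08, and adjusted p = 0.0988 with an estimated correlation). AT3G10040 fell by 3.87 ± 0.214, AT4G24110 by 3.8 ± 0.258, AT4G16000 by 3.75 ± 0.211, AT3G23170 by 3.3 ± 0.162 and AT2G20670 by 3.22 ± 0.255 (SE, n = 3 arrays per group). PDC2 fell by 2.11 and AT4G17260 by 1.93. The largest rises were in AT3G01830 (3.33 ± 0.313), AT1G72240 (3.14 ± 0.138), AT4G27654 (3.11 ± 0.285), AT5G46230 (3.07 ± 0.209) and AT2G44670 (3 ± 0.183). Glycolysis fell in 6 of 10 cases (6 adjusted over the list alone; median -0.48, adjusted p = 0.000108, and adjusted p = 0.0988 with an estimated correlation), where the deposited median was 0.38. Plastid-encoded genes had 7 falls among 69 (1 adjusted over the list alone; median -0.46, adjusted p = 0.00523, and adjusted p = 0.681 with an estimated correlation), where the deposited median was 0.39. Heat shock genes had a median of 0.22 (adjusted p = 0.67) and mitochondrion-encoded genes of -0.09 (adjusted p = 0.626). Mean-centred, 4301 probe sets rose and 4113 fell (3865 and 5063 with each array's median subtracted), against 19954 and 569 on the deposited log2 values. Replicate 1 of the polysomal recovery arrays had an actin control 3' minus 5' log2 difference, a measure of RNA quality, of 3.306. Replicates 2 and 3 had 1.605 and 1.888, and all polysomal recovery comparisons use this array. With 1 array or replicate number left out, 7397 to 8060 probe sets passed mean-centred.

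Against the 9 h air control, recovered polysomal RNA still showed AT1G53540 up by 7.18 ± 0.539, AT5G10040 by 6.74 ± 0.222, AT2G17850 by 6.03 ± 0.238, AT1G52560 by 5.92 ± 0.293 and AT3G29970 by 5.88 ± 0.27 (mean-centred; SE, n = 3 arrays per group). Core genes were up in 17 of 19 cases (17 adjusted over the list alone; median 2.41, adjusted p = 2.54e-21, and adjusted p = 0.00168 with an estimated correlation). All 5 heat shock genes were up (5 adjusted over the list alone; median 5.29, adjusted p = 5.32e-08, and adjusted p = 0.0407 with an estimated correlation). AT5G03230 (-3.44 ± 0.201), EXPA4 (-2.9 ± 0.27), AT3G53250 (-2.9 ± 0.354), AT4G24780 (-2.86 ± 0.187) and AT4G30170 (-2.86 ± 0.257) were furthest down. Ribosomal protein genes were down in 21 of 27 cases (23 adjusted over the list alone; median -0.58, adjusted p = 1.6e-12, and adjusted p = 0.0991 with an estimated correlation). Photosynthesis genes were down in 3 of 7 (4 adjusted over the list alone; median -0.24, adjusted p = 0.0371, and adjusted p = 0.167 with an estimated correlation). Mean-centred, 3890 probe sets were up and 4525 down, against 2746 and 7268 on the deposited log2 values.

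The polysomal change minus the total change asks which mRNAs moved in their association with polysomes. A rise or fall of this difference can come from either pool. At 2 h of hypoxia glycolysis and ribosomal proteins parted. Relative to the all-gene shift, glycolysis genes rose in 5 of 10 cases (7 adjusted over the list alone), with a median of 0.66 (adjusted p = 3.05e-07, and adjusted p = 0.0326 with an estimated correlation). AT1G76550 (1.12), AT1G12000 (0.88) and AT1G20950 (0.8), which encode phosphofructokinase subunits, and ENOC (0.7) were among them. On the deposited log2 values the glycolysis median was -0.16, so these genes lost less than most others on that scale. Ribosomal protein genes fell in 15 of 27 cases (16 falls and 2 rises adjusted over the list alone), with a median of -0.45 (adjusted p = 3.05e-07, and adjusted p = 0.303 with an estimated correlation), AT5G23900 by 1.26. Mitochondrion-encoded genes fell in 3 of 16 (3 adjusted over the list alone; median -0.41, adjusted p = 0.00213, and adjusted p = 0.298 with an estimated correlation). This went with their rise in total RNA at 2 h, as their polysomal list did not pass. Core hypoxia genes had a median of -0.03 (adjusted p = 0.549), AT4G27450 at 0.5 and AT3G03270 at -1.67. Heat shock genes had a median of 0.65 (adjusted p = 0.198, and 0.0392 with same-numbered arrays paired as differences). The largest relative rises were in AT5G04960 (1.87 ± 0.191), the peroxidase genes AT1G34510 (1.84 ± 0.21) and AT3G49960 (1.76 ± 0.243), EXPA18 (1.61 ± 0.195) and the glucosinolate transporter gene GTR2 (1.57 ± 0.252; SE from 3 arrays in each of 4 groups). NDB2 (1.19), EXPA7 (0.97), PDC2 (0.7) and PYK10 (0.66) also rose. AT5G04960 and EXPA18 were among the largest falls in total RNA at 2 h. Of the 287 probe sets with a relative rise of at least 2-fold, 223 fell in total RNA at 9 h and 22 rose. Of all probe sets 24.5% fell there. The largest relative falls were in AT3G55170 (-2.37 ± 0.338), AT1G33050 (-2.09 ± 0.362), AT2G07777 (-1.91 ± 0.4), AT1G76405 (-1.89 ± 0.271) and AT3G61100 (-1.89 ± 0.273). Mean-centred, 1679 probe sets rose and 1733 fell (287 and 481 at least 2-fold), against 55 and 18857 on the deposited log2 values, whose all-gene median was -0.821 and on which the calls of AT3G49960 and GTR2 ended in at least 1 leave-out.

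**Figure D3:**
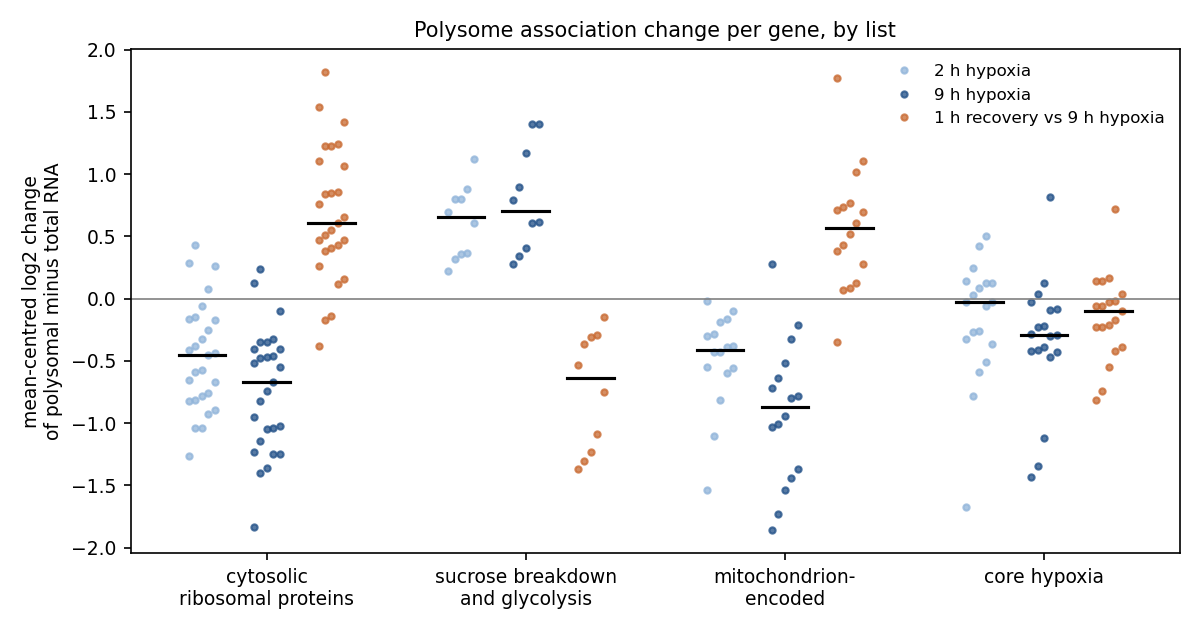
Mean-centred polysomal minus total log2 change of each gene of 4 lists at 2 h of hypoxia, at 9 h of hypoxia and on recovery against 9 h of hypoxia. Black bars are list medians.

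At 9 h of hypoxia the same groups changed, and the values are drawn in the figure of association changes. Glycolysis rose in 6 of 10 cases (9 adjusted over the list alone; median 0.7, adjusted p = 2.32e-07, and adjusted p = 0.0332 with an estimated correlation), AT1G76550 and AT1G12000 by 1.4 each and the phosphoglucose isomerase gene AT5G42740 by 1.17, where the deposited median was -0.3. Ribosomal protein genes fell in 18 of 27 (22 adjusted over the list alone; median -0.67, adjusted p = 1.76e-11, and adjusted p = 0.115 with an estimated correlation), AT5G23900 by 1.83 and AT3G04920 by 1.4. Mitochondrion-encoded genes fell in 11 of 16 (12 adjusted over the list alone; median -0.87, adjusted p = 4.83e-07, and adjusted p = 0.0332 with an estimated correlation), with ccb452 at -1.86, cox1 at -1.73 and nad5 at -1.54. Their mean rose by 1.06 ± 0.12 (SE) in total RNA, while their polysomal list did not pass. This fall thus follows total RNA and does not show a loss from polysomes. The core hypoxia genes had 3 falls among 19 (3 adjusted over the list alone) and a median of -0.29 (adjusted p = 0.0509, and 0.01 with same-numbered arrays paired as differences), AT3G03270 at -1.43 and AT1G33055 at -1.34. PDC2 rose by 1.18, AT4G17260 by 0.76, NDB2 by 1.5, EXPA7 by 1.51 and PYK10 by 0.82. The peroxidase genes AT4G26010 (3.22 ± 0.242), AT1G30870 (3.08 ± 0.288) and AT1G34510 (2.44 ± 0.21), AT5G04960 (2.79 ± 0.191) and AT5G26260 (2.46 ± 0.241) rose most (SE from 3 arrays in each of 4 groups). AT2G07777 (-2.82 ± 0.4), AT3G55170 (-2.59 ± 0.338), AT3G51500 (-2.48 ± 0.194), AT3G05810 (-2.4 ± 0.271) and AT1G33050 (-2.25 ± 0.362) fell most. AT4G26010 and AT1G30870, which rose here, were among the largest falls in total RNA at 9 h. Of the 751 probe sets with a relative rise of at least 2-fold, 66.7% fell in total RNA at 9 h, against 24.5% of all probe sets. The total change is subtracted in this difference, so the choice of the 751 by itself favours falls in total RNA. Mean-centred, 2616 probe sets rose and 2883 fell (751 and 940 at least 2-fold), against 168 and 19798 on the deposited log2 values, on which the calls of AT1G76550, AT1G12000, NDB2 and EXPA7 ended in at least 1 leave-out. Of the probe sets that rose at 2 h 1215 also rose at 9 h (193 expected for independent calls), and of those that fell 1441 also fell (220 expected). The 2 comparisons share no arrays, and their changes had a correlation of 0.791.

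Recovery reversed these association changes within 1 h. Against 9 h of hypoxia, ribosomal protein genes rose in 18 of 27 cases and 1 fell (20 and 1 adjusted over the list alone; median 0.61, adjusted p = 4.29e-10, and adjusted p = 0.191 with an estimated correlation), AT5G23900 by 1.82 and AT5G60670 by 1.54. Mitochondrion-encoded genes rose in 7 of 16 (7 adjusted over the list alone; median 0.57, adjusted p = 0.00187, and adjusted p = 0.191 with an estimated correlation), ccb452 by 1.77. This went with their fall in total RNA on recovery, as their polysomal list did not pass. Glycolysis fell in 5 of 10 (6 adjusted over the list alone; median -0.64, adjusted p = 1.47e-06, and adjusted p = 0.0553 with an estimated correlation), with AT5G42740 at -1.3 and AT1G76550 at -1.23, where the deposited median was 0.2. Heat shock genes had a median of -1.09 (adjusted p = 0.106, and 0.00484 with same-numbered arrays paired as differences). AT3G55170 (2.86 ± 0.338), AT3G05810 (2.69 ± 0.271), AT3G57320 (2.6 ± 0.252), AT1G51200 (2.48 ± 0.21) and the cold-regulated gene COR27 (2.38 ± 0.238) rose most. AT3G02840 (-2.26 ± 0.398), PDC2 (-1.83 ± 0.171), AT5G03610 (-1.78 ± 0.209), BGLU33 (-1.68 ± 0.232) and AT5G25930 (-1.67 ± 0.272) fell most (SE from 3 arrays in each of 4 groups). AT4G17260 fell by 1.15, NDB2 by 1.43 and PYK10 by 0.99. Mean-centred, 2553 probe sets rose and 2447 fell, against 18529 and 131 on the deposited log2 values, on which the calls of AT3G02840, AT5G25930, NDB2 and AT5G42740 ended in at least 1 leave-out. Of the 2616 probe sets that had risen at 9 h, 1642 fell, and of the 2883 that had fallen 2067 rose. Shared arrays alone give a correlation of -0.501 between these changes, where -0.834 was found.

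Against the 9 h air control, few association changes were left after recovery. AT4G26010 (3.51 ± 0.242), AT1G30870 (3.32 ± 0.288), AT5G04960 (2.89 ± 0.191), AT3G49960 (2.59 ± 0.243) and AT1G34510 (2.56 ± 0.21) stayed up, and AT3G53250 (-1.95 ± 0.501), AT1G33050 (-1.64 ± 0.362), AT3G62950 (-1.44 ± 0.221), nad4 (-1.37 ± 0.353) and AT1G19530 (-1.33 ± 0.327) stayed down (mean-centred; SE from 3 arrays in each of 4 groups). In total RNA AT4G26010 and AT1G30870 were among the largest falls of recovery against air. Core hypoxia genes fell in 2 of 19 cases (4 adjusted over the list alone; median -0.45, adjusted p = 4.94e-07, and adjusted p = 0.161 with an estimated correlation), AT1G33055 by 1.3. Mitochondrion-encoded genes fell in 3 of 16 (4 adjusted over the list alone; median -0.28, adjusted p = 0.000375, and adjusted p = 0.161 with an estimated correlation). Plastid-encoded genes had a median of -0.31 (adjusted p = 0.00274, and adjusted p = 0.709 with an estimated correlation). Ribosomal proteins (-0.05) and glycolysis (0.07) had an adjusted p of 0.376 each. Heat shock genes had a median of -0.84 (adjusted p = 0.145, and 0.00334 with same-numbered arrays paired as differences). Mean-centred, 256 probe sets rose and 72 fell (447 and 256 with paired differences), against 171 and 326 on the deposited log2 values. That sum of 497 was 931 with the replicate number as a block and 1360 with paired differences. It dropped to 320 without total recovery replicate 3, to 182 without replicate 1, to 229 without replicate 2 and to 81 without replicate 3. The calls of AT1G19530, nad4, AT3G53250 and AT1G33050 ended in at least 1 of these leave-outs.

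In air, the mRNAs least found in polysomal RNA were those of the plastid genome: all 69 plastid-encoded genes were lower in polysomal than in total RNA (69 adjusted over the list alone), with a mean-centred median of -4.89 (adjusted p = 2.76e-67, and adjusted p = 0.000995 with an estimated correlation). The largest differences were in psaA (-6.29 ± 0.381), psbB (-6.21 ± 0.253) and atpH (-6.17 ± 0.207; SE from 3 arrays in each of 4 groups). Mitochondrion-encoded genes were lower in 12 of 16 cases (13 adjusted over the list alone; median -0.87, adjusted p = 3.42e-08, and adjusted p = 0.0167 with an estimated correlation), nad4 by 3.14, ccb382 by 2.63 and nad1 by 2.47. Glycolysis genes were lower in 9 of 10 (9 adjusted over the list alone; median -0.51, adjusted p = 1.17e-06, and adjusted p = 0.0193 with an estimated correlation), and EXPA18 was at -2.09. Higher in polysomal RNA were AT2G25735 (2.16 ± 0.152), AT1G67860 (2.11 ± 0.158) and AT1G24575 (2.08 ± 0.108). Core hypoxia genes were higher in 11 of 19 cases and lower in 1 (11 and 2 adjusted over the list alone; median 0.56, adjusted p = 0.0113, and adjusted p = 0.34 with an estimated correlation). Ribosomal proteins had a median of 0.11, with 11 higher and 6 lower (11 and 6 adjusted over the list alone), while their test pointed down, so that median and test differ in sign (adjusted p = 0.839). Mean-centred, 6057 probe sets were higher and 5430 lower (8739 and 4651 with each array's median subtracted), against 2344 and 16507 on the deposited log2 values. The tagged RPL18B is a protein of cytosolic ribosomes.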

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

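The comparisons on deposited values and the test for compression near the floor of the arrays were written beforehand, and the mean-centred values, the direct comparison of hypoxic groups and the other tests of explanations were chosen only after the results were seen. The values below were marked because a change differed between 2 settings of the design or because measured values beside the main comparisons moved with a condition.

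The change against air differed between 9 h and 2 h in total RNA at 4147 probe sets, and 89 of them had passed in opposite directions at the 2 times. Group medians of that difference were 3.32 for heat shock genes, 0.33 for core hypoxia genes, 0.41 for mitochondrion-encoded genes, -0.36 for ribosomal proteins and -0.26 for nuclear photosynthesis genes. For photosynthesis genes the air controls moved by a median of 0.32 and the hypoxic groups by 0.06. For core hypoxia genes these medians were -0.33 and 0.13, with 8 rises and 5 falls between the hypoxic groups.

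The hypoxia response differed between polysomal and total RNA. At 2 h it did so at 18912 probe sets on the deposited log2 values and at 3412 when each array's mean was subtracted. At 9 h these counts were 19966 and 5499, for recovery against 9 h of hypoxia 18660 and 5000, and for recovery against 9 h of air 497 and 328. Mean-centred medians at 2 h were 0.66 for glycolysis, -0.45 for ribosomal proteins and -0.41 for mitochondrion-encoded genes. At 9 h they were 0.7, -0.67 and -0.87 in the same order, and on recovery from 9 h of hypoxia -0.64, 0.61 and 0.57. For recovery against 9 h of air, core hypoxia genes were at -0.45, plastid-encoded genes at -0.31 and mitochondrion-encoded genes at -0.28. Bacillus control probe sets, which were not part of any comparison, were higher by 1.07 (SE 0.25) on the total 9 h hypoxia arrays than on those of air.

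The first pattern weighed is that polysomal arrays lie below total arrays by an amount set by the condition. A constant put on all log2 values after hybridisation was not excluded, and the polysomal array levels go with it. From air to hypoxia the 5th percentile of these arrays fell from 2.871 to 2.043 at 2 h and from 2.864 to 1.921 at 9 h. The mean fell from 5.364 to 4.536 and from 5.358 to 4.342. Probe sets near the floor thus fell about as much as the mean, which argues against a loss from expressed mRNA alone. Hybridisation controls moved by -0.82 (SE 0.153) on polysomal arrays at 2 h, beside -0.83 in the array mean. Bacillus controls moved by -1 (SE 0.197) at 2 h and only -0.14 (SE 0.302) at 9 h. On total 9 h arrays they rose by 1.07 (SE 0.25), so they are no fixed reference. Less labelled RNA on the 2 h arrays would by itself leave or raise the hybridisation controls, where -0.82 was found. It could not be excluded, because a constant put on afterwards would lower the controls whatever the RNA amount. At 9 h the controls moved by -0.7 (SE 0.296) beside an array mean shift of -1.02, which could not tell the 2 apart. A smaller share of mRNA in polysomes under hypoxia may be open as well, and it is no rival of such a constant, which could itself stand for polysome content. The 9 h polysomal arrays stood at 0.371 of the total arrays on a linear scale, and no polysome content was used here. If the shift does hold polysome content, subtracting the array mean removes it.

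The second pattern is the set of 751 probe sets whose polysomal value rose at least 2-fold relative to total RNA at 9 h, such as AT4G26010, AT5G04960 and EXPA18. Of these, 66.7% fell in total RNA at 9 h, against 24.5% of all probe sets. They were chosen on a difference that subtracts this same total change, so a share above that of all probe sets follows in part from the choice. Most of these relative rises thus went with a fall in total RNA and need not be a gain in polysomal RNA. Compression near the floor of the arrays, a prediction written before its result was seen, was excluded for the set as judged by its median. The median polysomal level of the 751 under hypoxia was 3.48 above the 5th percentile. It was not excluded for each member: 76.4% lay more than 2 log2 units above that percentile, and 10.8% within 1 unit of it. Chance values of the total arrays, shared by every difference at 9 h, were excluded because the same probe sets had a median of 0.81 at 2 h, on other arrays.

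The third pattern is the rise of mitochondrion-encoded transcripts in total RNA at 9 h. An equal change in the priming of all organelle RNA was excluded, since their mean rose by 0.73 ± 0.16 (SE) more than that of plastid-encoded genes. A change that differs between the organelles was not, and the plastid-encoded mean moved by 0.33 ± 0.21. Bacillus controls rose by 1.07 (SE 0.25) on the same arrays, and a technical cause shared with them was not tested. More RNA degradation was not seen in the actin 3' minus 5' difference, the only control tested for it, which moved by -0.13 ± 0.19. No biological explanation was tested for any of these patterns.

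Regrouping the arrays of a comparison gives 10 splits for 3 against 3 arrays, too few for a share under 0.05, and the real grouping was 1 of them with the most probe sets. The real values for total RNA were 4144 (2 h), 10241 (9 h), 5644 (recovery against hypoxia) and 9130 (recovery against air). For polysomal RNA they were 20484, 21212, 20336 and 8860 in the same order, and for the association change 19845, 20521, 19432 and 991. The difference between 9 h and 2 h had 5027 and the 2 air controls 1591. In all of them the highest other split had 0 calls at a limma adjusted p under 0.05. For polysomal against total RNA in air the real grouping, with 18273, was 1 of 100 splits, and the highest other had 0. These are deposited values, where the shift of all polysomal arrays sets the outcome, so this cannot speak to single genes. Mean-centred, the real grouping had 10466 and the highest other of 100 splits again 0, a share under 0.05. On either scale other splits mix arrays of the groups compared, so real differences widen the spread within their groups. Few or 0 calls in them are thus no measure of how many calls chance would give.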

How the results depend on the processing

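Subtracting array means, alone and with a block, pairs or left-out arrays, pairs for polysomal against total RNA and the direct comparison of hypoxic groups were chosen after the results were seen, and all other settings were written before the data were examined. Between deposited and mean-centred values, group medians in polysomal comparisons can change sign, since all probe sets shift: glycolysis at 2 h was -0.26 and 0.57 in polysomal RNA and -0.16 and 0.66 in the association change. Of the genes named for association changes, AT1G76550, AT1G12000, AT1G20950, ENOC, AT4G27450, NDB2, EXPA7, PDC2 and PYK10 at 2 h and AT5G42740, AT4G17260, PDC2 and PYK10 at 9 h rose only when mean-centred, and AT1G76550, AT4G17260 and PYK10 fell on recovery from hypoxia only then. Some genes passed on both scales with opposite signs, such as NDB2 in polysomal RNA at 9 h, at -0.49 deposited and 0.53 mean-centred. Over the counts of passing probe sets, 53 values moved by over 1.5 times and 102 did not, and most that moved belong to comparisons with polysomal arrays, whose shift of all probe sets ends under any centring. Of 64 fixed gene list calls, 21 passed with an estimated correlation. In total RNA this estimate was 0.767 for heat shock genes, 0.488 for ribosomal proteins and 0.32 for plastid-encoded genes. It was 0.25 for glycolysis, 0.243 for core hypoxia, 0.176 for mitochondrion-encoded, 0.128 for nuclear photosynthesis and 0.059 for nuclear respiration genes. All lie above the preset of 0.01, so adjusted p values at the preset are too low where these estimates hold. The loss of list calls follows from this setting alone, and the cause of the other moves was not tested. With 3 arrays per group, calls of small changes depended on single arrays or whole replicate numbers, above all replicate 3. Leaving out a replicate number also makes every group smaller. Of the genes named, EIF4A-2 at 2 h and AUR1 at 9 h in total RNA lost their call when centred on the array median, and AT5G08570 at 2 h when quantile-normalized again.

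With the dim probe sets left out, polysomal RNA had 11617 calls at 2 h, 12239 at 9 h and 11442 on recovery against hypoxia. The association change had 9943, 11061 and 9583, and 309 on recovery against air, and polysomal against total RNA in air had 10363. With quantile normalization again the polysomal counts were 7580, 10591 and 8449, the association counts 3453, 5546 and 5006, and that of polysomal against total RNA 11283. Centred on the array median they were 7548, 12631 and 8928, then 3387, 5489, 4924 and 325 (recovery against air). Centred on the array mean they were 7578, 10886 and 8414, then 3412, 5499, 5000 and 328, and 11487 for polysomal against total RNA.

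With an adjusted p under 0.01, total RNA had 3003 calls at 2 h and 3146 on recovery against hypoxia, the association change on recovery against air 175, the difference between 9 h and 2 h 2588 and the air controls 1001. At least 2-fold changes in total RNA numbered 924 (2 h), 3353 (9 h), 882 (recovery against hypoxia) and 2651 (recovery against air). In polysomal RNA they were 6774, 11047, 6628 and 2547, and for the association change 5966, 10953, 6609 and 184. The difference between 9 h and 2 h had 1468, the air controls 348 and polysomal against total RNA 2771.

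With the replicate number as a block, the association change on recovery against air had 931 calls, and 1360 with paired differences, against 497. Where the numbers pair the arrays, the block changed no other call of a count or group than those given beside the results and, among added lists, branched-chain amino acid catabolism on recovery against air in total RNA (adjusted p 0.0517 without and 0.0416 with the block) and tetrapyrrole synthesis (0.0666 and 0.0412) and histones (0.0723 and 0.0486) at 9 h in polysomal RNA. Total and polysomal arrays of 1 condition are paired by number in all 15 pairs. As paired differences, the association change had 19748 (2 h), 20598 (9 h) and 19482 (recovery against hypoxia) calls and polysomal against total RNA 19405. Mean-centred they were 4662, 6770, 6215, 703 (recovery against air) and 12134. Besides the calls given beside the results, pairs brought under 0.05 branched-chain amino acid catabolism (0.0251 at 2 h, 0.0142 on recovery against hypoxia, 0.0192 in polysomal against total RNA), xyloglucan endotransglucosylases (0.0251 at 2 h) and calmodulin-like genes (0.0358 in polysomal against total RNA). In the comparisons left, arrays share only a number, and the block gave 10975 calls in total RNA at 9 h, 20898 (2 h) and 10657 (recovery against air) in polysomal RNA and 4894 for the difference between 9 h and 2 h. Between the hypoxic groups directly there were 7167.

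Leaving out 1 array or 1 replicate number gave 1913 to 4542 calls at 2 h in total RNA, with 3109 without total 2 h hypoxia replicate 3 and 1913 without replicate 3. Recovery against hypoxia in total RNA had 2640 to 4490, the lowest without replicate 3. The difference between 9 h and 2 h had 2047 to 4096 (2279 without replicate 2, 2047 without replicate 3), and the air controls 742 to 1371 (1016 and 742). The association change on recovery against air had 81 to 526: 320 without total recovery replicate 3, and 182, 229 and 81 without replicates 1, 2 and 3.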

Other observations

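The gene lists in this part were added after gene names and array-level summaries had been seen, and the test of the hypothesis at its end was chosen only after the results were seen.

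Genes of branched-chain amino acid catabolism rose in total RNA at both times: 5 of 9 at 2 h (median 0.51, adjusted p = 0.000706, and adjusted p = 0.163 with an estimated correlation) and 8 of 9 at 9 h, where 1 fell (median 0.78, adjusted p = 0.00464, and adjusted p = 0.349 with an estimated correlation). In polysomal RNA they fell on recovery in 8 of 9 cases (mean-centred median -0.78, deposited median 0.08, adjusted p = 0.000774, and adjusted p = 0.188 with an estimated correlation). Of 10 autophagy genes of ATG8 conjugation 5 rose at 2 h (median 0.44, adjusted p = 0.000706, and adjusted p = 0.163 with an estimated correlation) and 6 at 9 h (adjusted p = 0.0214, and adjusted p = 0.349 with an estimated correlation), ATG8D by 1.19. In air they were higher in polysomal than in total RNA in all 10 cases (mean-centred median 0.97, adjusted p = 5.4e-06, and adjusted p = 0.152 with an estimated correlation). Expansins fell in 9 of 18 cases at 2 h (median -0.46, adjusted p = 0.000706, and adjusted p = 0.0693 with an estimated correlation) and in 10 at 9 h, where 1 rose (adjusted p = 0.00464, and adjusted p = 0.115 with an estimated correlation), EXPA4 by 2.44. Tubulins fell in 6 of 7 cases at 2 h and 1 rose (median -0.5, adjusted p = 0.0131, and adjusted p = 0.163 with an estimated correlation), with TUB1 at -1.82 and TUA1 at 1.3 at 9 h. Cold and dehydration genes rose in 5 of 9 cases at 9 h (adjusted p = 0.0234, and adjusted p = 0.349 with an estimated correlation), COR27 by 3.67 and TIL by 3.35. Of 14 citrate cycle genes 4 fell at 2 h (adjusted p = 0.00526, and adjusted p = 0.163 with an estimated correlation).

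Co-chaperones rose in 8 of 14 cases at 9 h and 2 fell (adjusted p = 0.0228, and adjusted p = 0.349 with an estimated correlation), Hop3 by 3.23, Fes1A by 1.98 and HSA32 by 1.67. On recovery 3 of 14 genes of protein folding in the endoplasmic reticulum rose (adjusted p = 0.0264, and adjusted p = 0.247 with an estimated correlation), and BZIP60 of the unfolded protein response rose by 0.92. Tetrapyrrole synthesis was below air after recovery in 8 of 13 cases and above it in 1 (median -0.73, adjusted p = 0.00382, and adjusted p = 0.244 with an estimated correlation), HEME2 by 2.02. Calmodulin-like genes were above air in 4 of 7 cases after recovery and below it in 1 (adjusted p = 0.0279, and adjusted p = 0.379 with an estimated correlation), CML37 by 1.51. The list median was 0.65, and its highest member stood at 5.59. Histones fell in 3 of 8 cases on recovery (adjusted p = 0.0208, and adjusted p = 0.247 with an estimated correlation), HTB2 by 1.29. Glutathione S-transferases gained in polysome association at 9 h: 8 of 14 rose and 2 fell (mean-centred median 0.64, adjusted p = 0.00555, and adjusted p = 0.0188 with an estimated correlation), GSTU26 by 1.97, GSTU25 by 1.77 and GSTU28 by 1.58. On the deposited log2 values the list median was -0.36, and the calls of these 3 genes ended when at least 1 array or replicate number was left out, as did that of BZIP60 above. Of 47 UDP-glycosyltransferases 10 rose and 1 fell in the same comparison (mean-centred median 0.16, adjusted p = 0.0157, and adjusted p = 0.503 with an estimated correlation), UGT71C1 by 2.25, where the deposited median was -0.84. At 9 h in total RNA, adjusted p was 0.444 for xyloglucan endotransglucosylases, 0.619 for flavonoid synthesis and 0.514 for SWEET transporters.

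A hypothesis is that mRNAs induced by hypoxia are spared a relative loss from polysomes. The 577 probe sets that rose at least 2-fold in total RNA at 2 h had a median association change of 0.09 at 9 h (mean-centred, quartiles -0.37 and 0.53), which could not tell by the limits set. The median of all probe sets was 0.017. Of the 577, 68 passed with a rise and 82 with a fall, against 2616 and 2883 of all 22746. As a set they moved much like all probe sets, and no general sparing was seen. Whether hypoxia itself or another feature of the treatment gives these changes stays open in this design.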
